A study of Mus musculus with 24 samples.

How the data were processed

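RNA was extracted from macrophages sorted in bulk by flow cytometry from dura and diaphragm of wild-type mice perfused through the heart, and sequenced as short single-end reads from an unstranded kit, per the labels' protocols. The protocol text describes the dural preparation, and the digestion of the diaphragm is not given in the sources used here. The submitters' processing notes name STAR 2.4.0j, featureCounts, DESeq2 1.20.0 and the GRCm38 genome build, without saying which step made which file. The deposited table holds whole-number counts per gene made by the authors, and was read as raw counts although it is called normalised, since its values are whole and its column totals differ widely. It has 41388 Ensembl genes and 24 columns. Gene symbols came from a table of Ensembl names, found for 40254 genes, and coordinates from the GENCODE annotation of the same build. With an unstranded kit, reads of overlapping genes on opposite strands cannot be told apart, and reads shared between near-identical gene copies are uncertain.

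The labels place the 24 samples in 6 groups, but the column names match no title or subset of the labels. They show the tissue, and for dura a number (1, 3 or 4) and a mark (P4, P5 or P6). No column was assigned to a subset from its order or its values. The comparisons between subsets, the differences of these between tissues and the comparison of the labels with and without the suffix a, all fixed before the data were examined, were therefore not run, and neither were their alternatives. Dura against diaphragm over all libraries, and every alternative to it, was chosen after the column names were seen. The lists of marker and pathway genes, the identity panel and the rule for naming genes were fixed before the data were examined.

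Diaphragm columns with an added prefix were compared with the columns of the same number by a chi-square over genes with at least 20 counts in a pair, here 12307 to 13441 genes. The 6 pairs had ratios of chi-square to degrees of freedom from 1.008 to 1.169, close to the value of 1 that repeat reading of 1 library gives, and were summed. The 2 columns with fewer than 10000 counts were left out of the comparison. The resulting 16 libraries were 9 from dura and 7 from diaphragm. The 10 most abundant genes took between 8.43% and 14.4% of the counts of a library. A count of 0 over a whole tissue was given a limit of 3 counts over all its libraries, which covers counting error only, because reads without molecular identifiers are not independent molecules.

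Genes were filtered with filterByExpr, which kept 13136 genes. Library sizes were scaled with TMM factors, and dura was compared with diaphragm by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with no other term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are dura minus diaphragm on the log2 scale. Of 36 fixed gene lists, 32 had enough measured genes to be tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, and 13 passed. With an estimated correlation 1 passed. The fry test was run beside camera. Counts of list members across settings span 8 fits, namely edgeR with TMM, RLE or upper-quartile factors or library totals, voom, DESeq2, dural libraries summed per number, and diaphragm libraries 1 and 7 left out. Levels are CPM, counts scaled to a library total of 1000000 with TMM factors.

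The genes named were the 6 highest and 6 lowest fold changes past the threshold with no overlap between tissues and a mean log2(count + 1) of at least 5 in the higher tissue, with counts divided by the number of runs, skipping gene models without a proper symbol. To these came up to 4 called members of each list that passed camera or had at least 0.5 of its measured members called, and an identity panel of macrophage genes. A further rule, chosen after the results were seen, took the 8 highest and 8 lowest genes that met the same conditions and had a mean of at least 20 CPM in both tissues, because the first rule returned genes with almost no counts in one tissue. The genes Ccl12, Nfkbiz and Klrk1 were named after their values were seen. Some genes that the rule takes are not reported here.

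The test was checked on simulated counts drawn from the real means, library sizes and dispersions, with 12926 genes tested. Of 99 genes changed by a log2 fold change of 1, 52.5% were recovered, and of 99 changed by 2, 71.7% were recovered, with 7 unchanged genes called. Simulated libraries were drawn independently around the mean of each gene over all libraries, without the clusters seen among the real ones. The number of false calls therefore does not measure error where libraries cluster or share a source. Alternatives were RLE and upper-quartile factors, library totals, DESeq2 1.42.0, limma-voom, limma on log2(CPM + 1) with a pseudocount of 1, other filters, other treatments of the repeat runs and the near-empty columns, 2 surrogate variables from sva 3.50.0, dural libraries summed per number or with the number as a random term, each mark left out, diaphragm libraries 1 and 7 left out, and each library left out.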

Results

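Macrophages sorted from the dura mater, the outer membrane around the brain, and from the diaphragm, the muscle sheet between chest and abdomen, were profiled by RNA sequencing. The mice were wild-type C57BL/6 animals of 17 weeks at steady state, per the labels. The title of the series speaks of T cell transfer into RAG-1 deficient mice, whereas the labels of these samples name wild-type animals at steady state. The labels place 24 samples in 6 groups, made of 3 macrophage subsets (C1, C2 and C3) in each tissue, with 3 samples per subset in dura and 5 in diaphragm. The markers that define the subsets are not given in the sources used here. The column names of the count table give the tissue but match no subset, so the subsets were not compared, and the comparison made here is dura against diaphragm over all subsets together.

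The table held 9 dural columns and 15 diaphragm columns. Of the diaphragm columns, 6 carried an added prefix, and each of these matched the column of the same number so closely that both were read as 1 library sequenced in repeat runs. The ratio of chi-square to degrees of freedom lay between 1.008 and 1.169 in these 6 pairs and was at least 10.56 in every other pair of same-tissue columns with at least 10000 counts each. Counts within a pair were therefore added and counted as 1 sample; of the 6 pairs, the pair of number 1 had the highest ratio and the next had 1.035. A further 2 diaphragm columns, with totals of 1496 and 2115 counts, were left out. This left 9 dural libraries with 10457920 to 24077834 counts (median 12765528) and 7 diaphragm libraries with 11053351 to 30132295 counts (median 23498989). The dural columns carry 3 numbers crossed with the marks P4, P5 and P6, so the 9 dural libraries need not come from separate animals. The 7 diaphragm libraries need not either, and no fit grouped them by a shared source. The labels do not say that samples came from separate animals, and p-values measure only the spread between these libraries. Tissue also cannot be told apart from any batch that differed between the tissues.

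Dural macrophages had more RNA of the fractalkine receptor Cx3cr1, the lysophosphatidylserine receptor Gpr34 and the mannose receptor Mrc1 than diaphragm macrophages. Diaphragm macrophages had more RNA of the cytokines Il6 and Il1a, the neutrophil attractant Cxcl1, the secreted protein Retnla, and of many genes of cholesterol synthesis and glycolysis. The calls of these last 2 lists were lost with an estimated correlation (adjusted p = 0.214 and 0.303 with an estimated correlation). Summed glycolysis genes were at 2100 and 2070 CPM in diaphragm libraries 1 and 7, within the dural range of 1500 to 2150. Cx3cr1 (ENSMUSG00000052336, GRCm38 chromosome 9, 119901616 to 120069879, minus strand) stood at 1318 ± 166 CPM (counts scaled to a library total of 1000000; SD, n = 9) in dura and 390.3 ± 162 (n = 7) in diaphragm. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, plus strand) stood at 53.27 ± 47.5 CPM in dura and 2484 ± 1210 in diaphragm. Both genes separated every dural library from every diaphragm library. The liver gene Alb and the muscle genes Mb and Tnnt3 were present in all 7 diaphragm libraries and at or near 0 in dura, although some other liver and muscle genes, such as Ttr and Actn3, were not lower in dura. The leading transcripts of meninges and bone in dura had no counts in diaphragm.

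Of 13136 genes tested with edgeR's quasi-likelihood test, 3472 passed a Benjamini-Hochberg adjusted p of 0.05, of which 1465 were higher and 2007 lower in dura. Among the genes tested, 906 (6.9%) showed no overlap between the libraries of the tissues, where chance gives 0.017% for independent libraries. The libraries need not be independent, so that rate is nominal. Of the called genes, 1345 differed by a log2 fold change of at least 1. The biological coefficient of variation was 0.489. The share of called genes that were higher in dura was 42.2%, and it was 54.3% with upper-quartile factors and 61% with library totals alone, which moved the median log2 fold change of all genes to 0.124. When the 9 dural libraries were summed into 1 library for each of the 3 numbers in their names, 1259 genes were called, and 2143 were called without the dural libraries marked P5.

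Called genes with a mean of at least 20 CPM in both tissues and no overlap between the libraries of the tissues were ranked by fold change. This rule was set after the results were seen, and it does not show that the macrophages themselves carried these transcripts. On the dural side, H19, an imprinted long noncoding RNA, was higher by 3.15 ± 0.57 on the log2 scale (SE; edgeR adjusted p = 0.000675). Within each tissue, H19 was highest in the libraries where fibroblast marker genes were highest. In dura it was at 557 to 743 CPM in those marked P4 and 126 to 349 in the rest. In diaphragm it was at 113 and 78.8 CPM in libraries 1 and 7 and 12.3 to 36.4 in the rest. H19 was followed by Sesn1, a stress-induced sestrin (1.89 ± 0.26, edgeR adjusted p = 5.15e-05), and Cx3cr1 (1.76 ± 0.22, edgeR adjusted p = 1.99e-05). The sphingosine 1-phosphate receptor S1pr2 (1.54), Nfxl1 (1.53), Gpr34 (1.53), the organic anion transporter Slco2b1 (1.51) and the oxysterol receptor Gpr183 (1.43) came next, all past the edgeR threshold. On the diaphragm side, Retnla had a log2 fold change, dura minus diaphragm, of -5.54 ± 0.66 (edgeR adjusted p = 1.39e-05). The membrane protein gene Emp1 stood at -4.68 ± 0.28 and the matrix protein gene Ecm1 at -3.86 ± 0.36. The urokinase receptor Plaur (-3.48), Cxcl1 (-3.42), Il1a (-3.38), the transglutaminase Tgm2 (-3.37) and the guanine deaminase Gda (-3.30) were also lower in every dural library than in every diaphragm library.

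**Figure D1:**
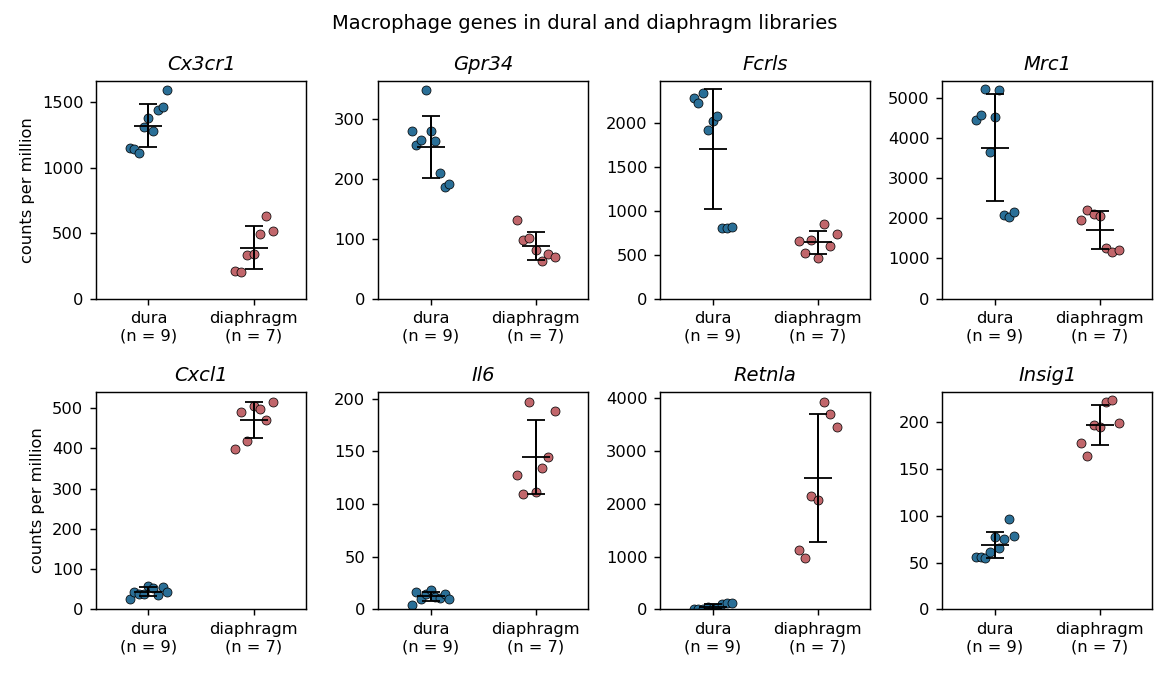
CPM (linear axis from 0) of 8 macrophage genes in each of the 9 dural and 7 diaphragm libraries; points are libraries, the long dash is the mean and the bars span 1 SD. Cx3cr1 was at 1318 CPM in dura against 390.3 in diaphragm, and Cxcl1 at 43.88 against 470.8, with no library of one tissue inside the range of the other; Mrc1 and Fcrls overlapped.

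Inflammatory cytokine and chemokine genes were mostly lower in dura. Of 19 measured members of this list, 13 were lower, 2 were higher and 4 did not pass the test (camera adjusted p = 3.97e-10; adjusted p = 0.0784 with an estimated correlation). Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) stood at 12.29 ± 4.31 CPM in dura and 144.4 ± 35 in diaphragm, a log2 fold change of -3.55 ± 0.24 (edgeR adjusted p = 4.54e-08). Cxcl1 stood at 43.88 ± 10.6 and 470.8 ± 45.4 CPM (edgeR adjusted p = 1.82e-10), and Il1a at 32.35 ± 16.2 and 337.2 ± 113 CPM. Cxcl3, a chemokine of the same family as Cxcl1, was at -4.60 on the log2 scale. The genes Ccl12 and Nfkbiz were higher in dura, by 1.41 and 0.58. Adjusted over the list alone, 3 members were higher and 13 lower. Skeletal muscle genes were higher in the same diaphragm libraries, at a summed 306.9 ± 83.5 CPM against 14.11 ± 5.02 in dura.

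Immediate early genes, which tissue digestion is known to induce, were not called as a list by camera, which tests a shift in 1 direction. Members that move both ways can cancel in it. Fry's test for any change in either direction gave an unadjusted p of 6.55e-13. That test passes if members of a list differ at all, and 3472 of 13136 genes were called. It gave 1.74e-12 for the pan-macrophage list and 8.26e-11 for the lipid and lysosome list, which camera did not call either. It therefore does not set the immediate early list apart. Of 18 measured members, 8 were higher in dura and 3 lower (camera adjusted p = 0.304; 4 to 8 and 3 to 4 across settings). Jun, a subunit of the transcription factor AP-1, was at 2723 ± 448 CPM in dura and 1264 ± 276 in diaphragm, and the antiproliferative gene Btg2 was at 2830 ± 294 and 1264 ± 247. The heat shock genes Hspa1a and Hspa1b went the other way, with log2 fold changes of -2.14 ± 0.30 and -3.18 ± 0.40 (edgeR adjusted p = 7.41e-05 and 2.51e-05). These 2 genes are near-identical copies, and reads between them cannot be assigned with certainty.

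Of 16 measured genes of cholesterol synthesis and uptake, 13 were lower and none was higher (camera adjusted p = 7.32e-08; adjusted p = 0.214 with an estimated correlation). Insig1, a regulator of sterol sensing, was at 68.99 ± 13.9 CPM in dura and 197.3 ± 21.6 in diaphragm, and Fdps, an enzyme of the mevalonate route, at -1.58 on the log2 scale. Of 15 glycolysis genes, 12 were lower and none was higher (camera adjusted p = 1.1e-06; adjusted p = 0.303 with an estimated correlation). Among them, the lactate transporter Slc16a3 was at -2.51 ± 0.42 and the hexokinase Hk2 at -1.05 ± 0.14. The summed glycolysis list was at 3290 to 3350 CPM in diaphragm libraries 3, 9 and 6. Libraries 1 and 7 (2100 and 2070) lay within the dural range of 1500 to 2150. The summed cholesterol list was at 1240 to 1310 CPM in libraries 3, 9 and 6 and 704 to 821 in the other diaphragm libraries, against 393 to 566 in dura. With the dural libraries summed per number, 4 of the cholesterol genes and 5 of the glycolysis genes were called. Of 17 oxidative phosphorylation genes, 4 were lower in dura, but 1 was lower with upper-quartile factors and with library totals alone none was lower and 1 higher (camera adjusted p = 0.152).

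The iron and heme list had 4 lower and no higher members among 13 (camera adjusted p = 0.0136; adjusted p = 0.592 with an estimated correlation). The summed list was at 12200 and 12000 CPM in diaphragm libraries 2 and 8, against 7730 to 8800 in the others and 6290 to 8300 in dura. Hmox1, which degrades heme, was at 313.8 ± 63.9 CPM in dura and 1058 ± 432 in diaphragm. Hpx, the member with the most negative fold change (-9.12), encodes a plasma protein made by liver, and Tfrc and Slc48a1 were at -0.83 and -0.41. With library totals alone, 1 of the 13 was higher and 2 were lower. The calls of Tfrc and Slc48a1 ended with library totals (edgeR adjusted p = 0.057 and 0.131), without the dural libraries marked P6 (edgeR adjusted p = 0.0933 and 0.0773) and when the dural libraries were summed per number. That of Tfrc also ended without those marked P4 (edgeR adjusted p = 0.0743), with the dural number as a random term (limma adjusted p = 0.0557), without diaphragm library 2 (edgeR adjusted p = 0.0504) and without libraries 1 and 7 (edgeR adjusted p = 0.0819). Alternative activation genes went both ways, with 3 higher and 5 lower of 14 (camera adjusted p = 0.303; 3 to 4 and 2 to 6 across settings). Lipid and lysosome genes also split, with 3 higher and 6 lower of 17 (camera adjusted p = 0.665, with 1 to 3 and 2 to 6 across settings). Fabp4, a fatty acid carrier, was at 3.655 ± 1.81 CPM in dura and 53 ± 49.2 in diaphragm. The diaphragm mean rested mostly on libraries 1 and 7 (143 and 99.5 CPM), where endothelial genes were also highest. The other diaphragm libraries, at 12.7 to 41.7 CPM, still lay above every dural library.

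Marker lists of myeloid cells shifted between the tissues. Of 9 measured genes typical of microglia, the macrophages of the brain, 7 were higher in dura and none was lower (camera adjusted p = 0.000587; adjusted p = 0.0784 with an estimated correlation). Gpr34 was at 254.3 ± 51.4 CPM in dura and 88.22 ± 23.9 in diaphragm, and Fcrls at 1703 ± 683 and 643.7 ± 131. The summed microglia list was at 2370 to 4620 CPM in dura. In diaphragm it was at 3750 CPM in library 1 and 1440 to 2330 in the others. With the dural libraries summed per number, 2 of the 9 genes were called, and voom called 5. The calls of Tmem119 (1.16) and Siglech (1.73) were among those lost when summed. That of Tmem119 also ended without the libraries marked P6 (0.67, edgeR adjusted p = 0.125). That of Siglech ended without those marked P4 or P5 (edgeR adjusted p = 0.189 and 0.135), with voom (voom adjusted p = 0.0774) and when any of 9 single libraries was left out (edgeR adjusted p from 0.0529 to 0.0672). Of 18 classical monocyte genes, 11 were lower in dura and none was higher (camera adjusted p = 1.83e-05; adjusted p = 0.203 with an estimated correlation). Plac8 was at 6.911 ± 5.92 CPM in dura and 95.01 ± 25.2 in diaphragm, fibronectin (Fn1) at 84.55 ± 109 and 1160 ± 675, and the lectin Clec4e at 9.38 ± 5.76 and 120.2 ± 74.6. Fn1 was at 366 CPM in dural library 1P4 (others 13.7 to 115), above diaphragm libraries 2 and 8 (224 and 317). It was at 1000 and 1730 CPM in diaphragm libraries 1 and 7, and at 1270 to 1810 in libraries 3, 9 and 6. Libraries 1 and 7 had the highest summed fibroblast genes and the lowest Ccr2 (19.7 and 23.7 CPM) of the diaphragm libraries. The summed classical monocyte list was at 5250 to 5660 CPM in diaphragm libraries 3, 9 and 6 and at 3120 in library 7. Libraries 1, 2 and 8 (2400, 1580 and 1590) lay within the dural range of 775 to 2850. Fn1 alone gave 1000 and 1730 CPM of the sums in libraries 1 and 7, so these sums need not reflect monocytes. The monocyte genes Ccr2 and Ly6c2 did not pass the test, with log2 fold changes of 0.45 ± 0.93 and -1.17 ± 0.73 (edgeR adjusted p = 0.761 and 0.257). Of 11 nonclassical monocyte genes, 6 were lower, among them Treml4 and Itgal (camera adjusted p = 0.00235; adjusted p = 0.118 with an estimated correlation). With the dural libraries summed per number, 6 classical and 3 nonclassical monocyte genes were called.

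Large peritoneal macrophage genes were lower in dura for 7 of 11 measured members and higher for none (camera adjusted p = 0.0173; adjusted p = 0.545 with an estimated correlation). With the dural libraries summed per number, 1 of them was called. The lipoxygenase Alox15 was at 0.2354 CPM in dura and 27.72 ± 40.9 in diaphragm, and Prg4, a lubricating secreted protein, at 0.2682 and 34.55 ± 50.3. In dura, Prg4 was at 1.13 CPM in library 1P4 and 0 to 0.508 in the others. Both diaphragm means rested on libraries 1 and 7. There Alox15 was at 91.9 and 83.1 CPM against 1.9 to 6.11 in the other 5, and Prg4 at 98.5 and 117 against 1.98 to 9.06. The fibroblast genes were highest in the same libraries, at a summed 23900 and 12300 CPM. Both calls were lost with limma-voom (adjusted p = 0.156 for Alox15 and 0.211 for Prg4 by voom), that of Alox15 also with the dural libraries summed (edgeR adjusted p = 0.0535). Of 13 conventional dendritic cell genes, 1 was higher and 4 were lower (camera adjusted p = 0.0421; adjusted p = 0.545 with an estimated correlation), and 2 to 7 were lower across settings. Their summed level was 1390, 1180 and 1430 CPM in diaphragm libraries 3, 9 and 6, while libraries 1, 7, 2 and 8 (311, 300, 419 and 375) lay within the dural range of 277 to 614. The transcription factor Irf4 was at 21.01 ± 4.8 CPM in dura and 94.16 ± 47.9 in diaphragm. Ccr7, a receptor of migrating dendritic cells, was at 3.154 ± 3.57 and 115.5 ± 126, with 243, 209 and 289 CPM in libraries 3, 9 and 6 and at most 43.1 in the others, and its call ended with limma-voom (voom adjusted p = 0.59) and with the dural libraries summed (edgeR adjusted p = 0.124).

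**Figure D2:**
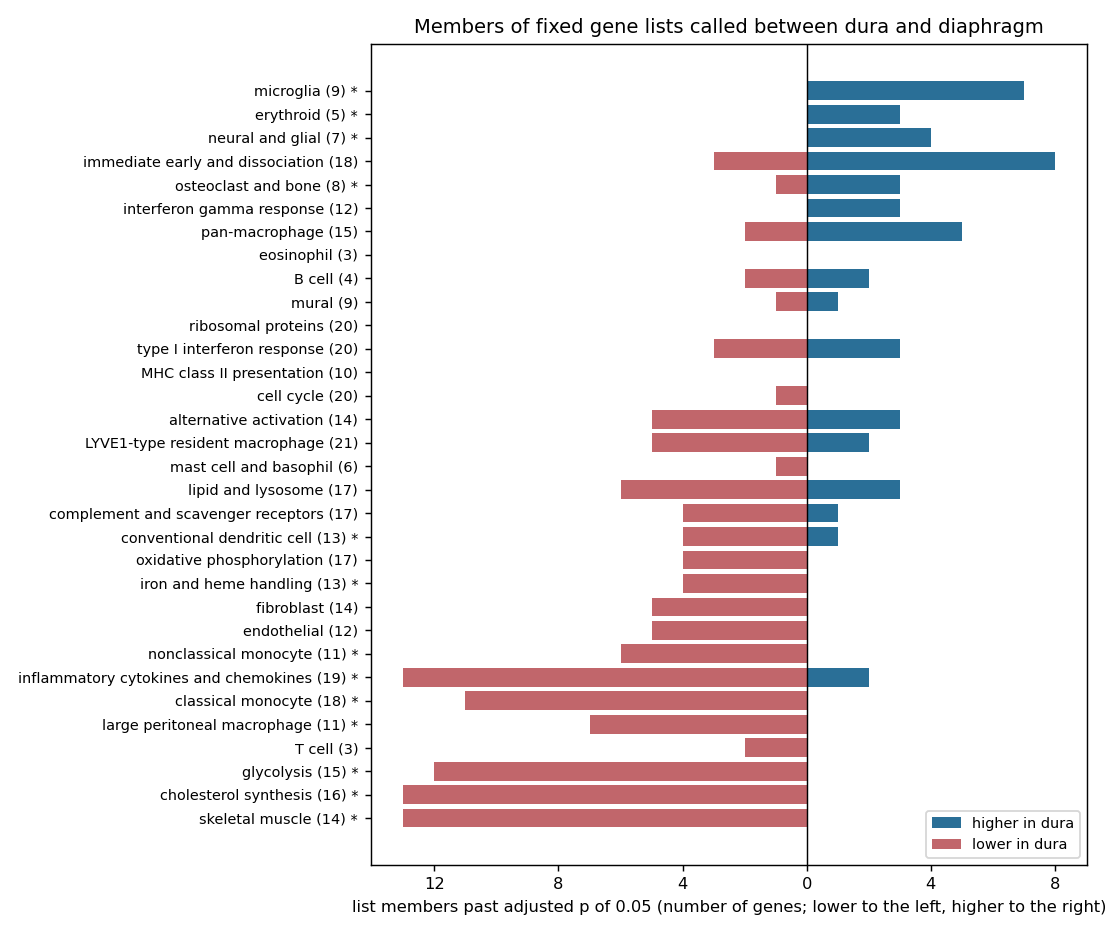
Number of members of each fixed gene list that passed an edgeR adjusted p of 0.05, to the right of 0 for genes higher in dura and to the left for genes lower in dura; the number in brackets is the number of measured members, and a star marks lists with a camera adjusted p under 0.05. The skeletal muscle list had 13 lower members of 14 and the microglia list 7 higher members of 9.

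Several macrophage identity genes differed between the tissues, and most spread widely among the libraries of each tissue. The resident macrophage markers Lyve1, a hyaluronan receptor, and Timd4, a phosphatidylserine receptor, had log2 fold changes of -2.63 ± 0.75 and -3.02 ± 0.82 (edgeR adjusted p = 0.0157 and 0.0113). The call of Timd4 ended when the dural libraries were summed per number (adjusted p = 0.0911 by edgeR), and those of both genes ended without the libraries marked P5 (adjusted p = 0.0963 for Lyve1 and 0.0692 for Timd4 by edgeR). Mrc1 was higher in dura by 1.14 ± 0.25 (edgeR adjusted p = 0.00271). The lineage receptors Csf1r and Adgre1 were higher by 0.43 ± 0.15 and 0.44 ± 0.13 (edgeR adjusted p = 0.0396 and 0.0174), and both calls ended with the summed dural libraries and without those marked P5 (adjusted p = 0.177 for Csf1r and 0.11 for Adgre1 by edgeR). Without diaphragm libraries 1 and 7, the calls of Lyve1, Csf1r and Adgre1 ended (adjusted p = 0.0616, 0.0847 and 0.0677 by edgeR). The call of Csf1r also ended when any of 10 single libraries was left out (edgeR adjusted p from 0.0514 to 0.0805). Folr2 and Itgax did not pass the test, at -1.34 ± 0.60 and -1.73 ± 0.92 (edgeR adjusted p = 0.11 and 0.18). With 2 surrogate variables Folr2, Itgax and Ccr2 passed it (edgeR adjusted p = 0.00742, 0.0087 and 0.00749), as did Folr2 with repeat runs as separate libraries (edgeR adjusted p = 0.0401) and Itgax without the libraries marked P6 (edgeR adjusted p = 0.0122). Across the list of LYVE1-type resident macrophages, 2 of 21 members were higher and 5 lower (camera adjusted p = 0.805; 1 to 3 and 2 to 5 across settings).

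Antigen presentation genes showed no tissue difference that passed the edgeR test over all libraries. Of 10 MHC class II genes none was called by edgeR or voom, 1 was called lower by DESeq2 and 2 without diaphragm libraries 1 and 7, and 2 were lower at an unadjusted p under 0.05 (camera adjusted p = 0.805). H2-Ab1 was at 8887 ± 6340 CPM in dura and 9960 ± 7760 in diaphragm, and Cd74, the invariant chain, at 18410 ± 13100 and 21810 ± 16700. The log2 fold changes of both genes, -0.17 ± 0.79 and -0.24 ± 0.74, were positive under some other settings. The SDs were near the means because libraries of the same tissue lay far apart. H2-Ab1 ranged from 942 to 1100 CPM in the 3 libraries marked P4, from 9640 to 10400 in those marked P5 and from 15000 to 15900 in those marked P6. In diaphragm it was 318 and 391 CPM in libraries 1 and 7, 8390 and 8140 in libraries 2 and 8, and 18000, 16900 and 17600 in libraries 3, 9 and 6. A tissue difference within any 1 subset is therefore not measured by this comparison. The mix of H2-Ab1 levels was uneven between the tissues, and the comparison does not adjust for it.

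**Figure D3:**
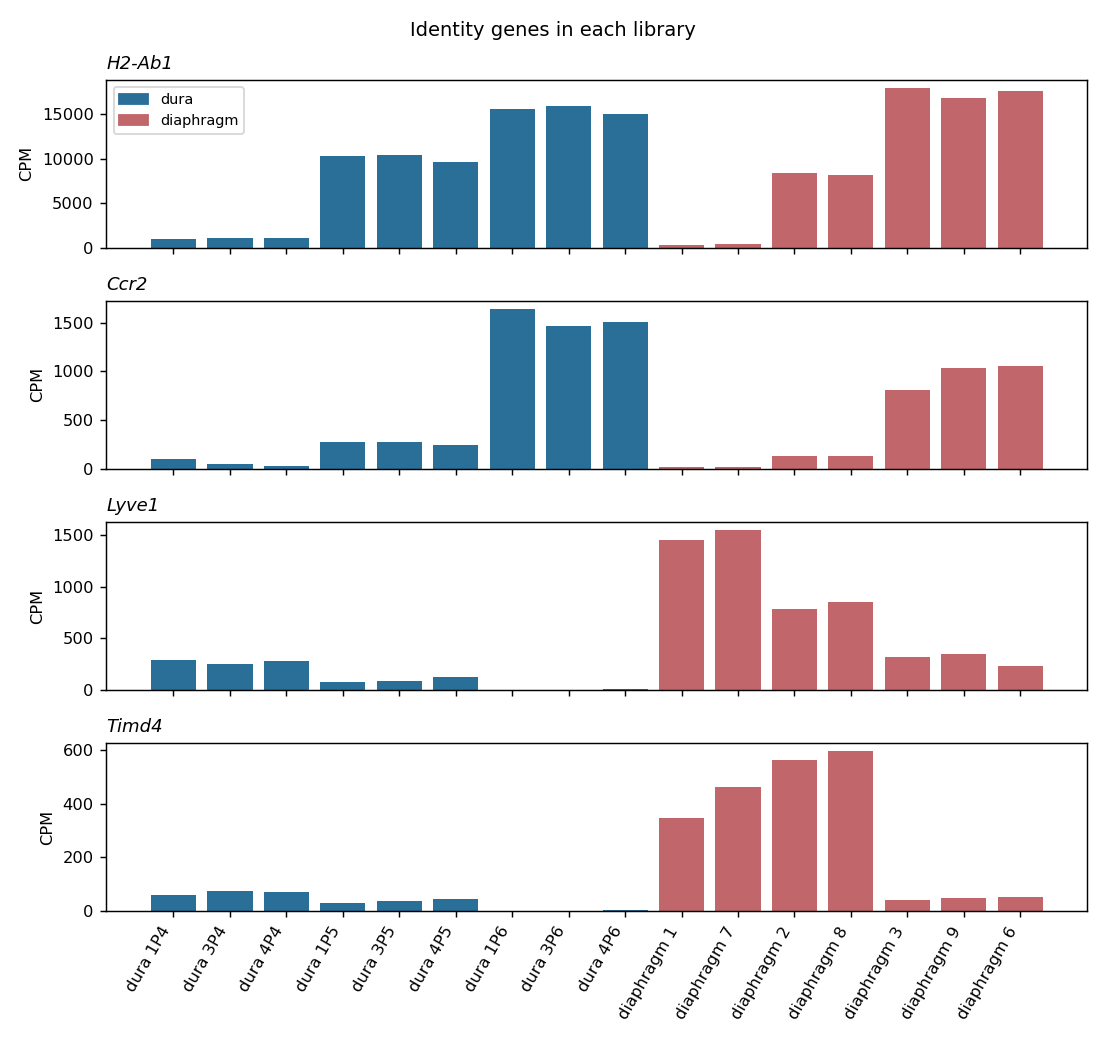
CPM (linear axes from 0) of H2-Ab1, Ccr2, Lyve1 and Timd4 in each library, named by tissue and by the number and mark of its column. H2-Ab1 spanned 942 to 15900 CPM among dural libraries and 318 to 18000 among diaphragm libraries, and Lyve1 was at 1450 and 1550 CPM in diaphragm libraries 1 and 7 against 229 in library 6.

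Interferon, ribosomal and cell cycle lists did not pass the list test. Of 20 type I interferon response genes 3 were higher and 3 lower (camera adjusted p = 0.706; 0 to 6 and 2 to 4 across settings), and of 12 interferon gamma response genes 3 were higher (camera adjusted p = 0.3; 1 to 4 across settings, with at most 1 lower). Of 20 ribosomal protein genes none was called by edgeR, voom or DESeq2, and 1 was lower at an unadjusted p under 0.05 (camera adjusted p = 0.258). Of 20 cell cycle genes 1 was lower in dura (camera adjusted p = 0.204; 0 to 4 across settings, with at most 1 higher). The pan-macrophage list had 5 higher and 2 lower members of 15 (camera adjusted p = 0.498; 2 to 7 and 1 to 4 across settings), and complement and scavenger receptors had 1 higher and 4 lower of 17 (camera adjusted p = 0.282; 0 to 1 and 1 to 4 across settings).

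Transcripts of other tissues marked the libraries by their origin. Albumin (Alb, ENSMUSG00000029368, chromosome 5, 90460897 to 90476602), the main plasma protein of liver, was at 367.6 ± 146 CPM in diaphragm and 0.03829 CPM in dura, a log2 fold change of -13.27 ± 0.50 (edgeR adjusted p = 4.04e-11). Myoglobin (Mb), the oxygen store of muscle, had no count in dura and was at least 1480-fold higher in diaphragm, taking 3 counts over all dural libraries as the limit that a count of 0 allows. By the same limit the liver genes Ahsg, Serpina3k, Serpina1b and Fgb were at least 1240-fold, 1010-fold, 652-fold and 640-fold higher in diaphragm. Serpina3k and Serpina1b belong to families of close copies, between which reads can be shared. The skeletal muscle list was lower in dura for 13 of 14 members (camera adjusted p = 2.5e-33; adjusted p = 0.000272 with an estimated correlation). It was the only list whose call held with an estimated correlation.

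In dura, the prostaglandin D synthase Ptgds, expressed in meninges, was at 39.67 ± 36 CPM and had no count in diaphragm, so that it was at least 1990-fold higher in dura. The transcription factors Zic1 and Zic2, the connexin Gjb6, the potassium channel subunit Kcns1 and Clic6 were at least 1250-fold, 358-fold, 690-fold, 414-fold and 409-fold higher in dura by the same limit. The bound of Clic6 rested on library 1P6 and was 147-fold without it. Sp7, the osteoblast transcription factor, stood at 4.345 ± 2.37 CPM in dura and the bone matrix gene Ibsp at 2.85 ± 1.69, and neither had a count in diaphragm. The osteoclast and bone list had 3 higher and 1 lower member of 8 (camera adjusted p = 0.0423; adjusted p = 0.317 with an estimated correlation). Across settings 3 to 4 were higher and 0 to 1 lower, and the lower call ended when any of 8 single libraries was left out. The summed bone list was at 223.3 ± 141 CPM in dura and 264.4 ± 126 in diaphragm, opposite in sign to its test. The neural and glial list had 4 higher and no lower members of 7 (camera adjusted p = 0.0136; adjusted p = 0.0784 with an estimated correlation), among them S100b (23.31 ± 12.2 CPM in dura, 0.5615 in diaphragm). With the dural libraries summed per number 2 were called, and the summed level of the list was 420.3 ± 123 CPM in dura and 500.6 ± 94 in diaphragm, opposite in sign to its test. The diaphragm mean of S100b rested mostly on library 1 (2.64 CPM, others 0 to 0.923). The erythroid list had 3 higher members of 5 (camera adjusted p = 0.0136; adjusted p = 0.545 with an estimated correlation), and none was called with the dural libraries summed per number.

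**Figure D4:**
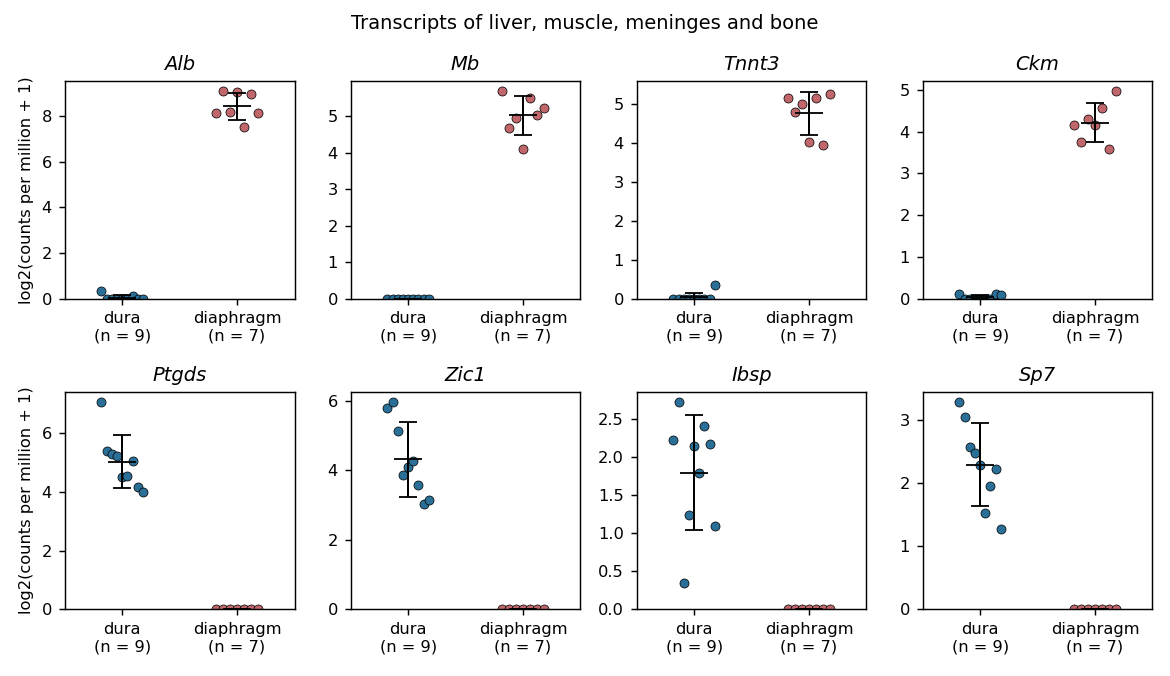
Values of log2(CPM + 1) in each of the 9 dural and 7 diaphragm libraries for liver (Alb), muscle (Mb, Tnnt3, Ckm), meningeal (Ptgds, Zic1) and bone (Ibsp, Sp7) genes; points are libraries, the long dash is the mean and the bars span 1 SD. Alb averaged 367.6 CPM in diaphragm and 0.03829 CPM in dura, and Ptgds averaged 39.67 CPM in dura with no count in diaphragm.

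Stromal marker lists did not pass the list test. Of 14 fibroblast genes 5 were lower in dura (camera adjusted p = 0.225), and of 12 endothelial genes 5 were lower (camera adjusted p = 0.212), while voom called 1 fibroblast and no endothelial gene. Most of these lower calls rested on diaphragm libraries 1 and 7. There the fibroblast genes summed to 23900 and 12300 CPM, against 942 to 1680 in the other 5 and 725 to 5780 in dura. Endothelial genes summed to 1510 and 1470 CPM in them, 504 and 552 in libraries 2 and 8, and at most 240 in dura. Without these 2 libraries, 5 fibroblast genes were higher and 2 lower in dura, and 2 endothelial genes were higher and 1 lower. Of 9 mural genes 1 was higher and 1 lower (camera adjusted p = 0.486), with 3 higher under upper-quartile factors and library totals, 4 higher by DESeq2 and 4 higher without diaphragm libraries 1 and 7. Few lymphocyte genes could be measured. Of 3 T cell genes 2 were lower (camera adjusted p = 0.303), but none by voom, and 1 of these calls ended when any of 11 single libraries was left out. Of 4 B cell genes 2 were higher and 2 lower (camera adjusted p = 0.706), and none was called by edgeR with the dural libraries summed per number. Mast cell and basophil genes had 1 lower member of 6 (camera adjusted p = 0.931, with 0 to 1 across settings). None of 3 eosinophil genes was called by edgeR with TMM factors over all libraries (camera adjusted p = 0.828). With library totals 1 was higher, and 1 was lower by voom and without diaphragm libraries 1 and 7. DESeq2 called 1 higher and 1 lower, as did an unadjusted p under 0.05. The mesothelial, NK cell, neutrophil and sex-linked lists each had 1 measured gene, and none was called by edgeR or voom over all libraries, while the mesothelial gene was higher and the NK cell gene lower without diaphragm libraries 1 and 7; DESeq2 and an unadjusted p under 0.05 each called 1, the NK cell gene Klrk1.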

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

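The tests reported in this part and in the other observations were chosen or worded after the results were seen, except that of transcription by 1 macrophage subset, which was stated before.

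Liver and muscle transcripts were present in all 7 diaphragm libraries. Of 12 tested genes of a separate hepatocyte list, 8 (66.7%) were higher in every diaphragm library than in every dural library, as were 11 of 14 skeletal muscle genes (78.6%). Alb, outside these lists of tested genes, averaged 367.6 CPM in diaphragm, and Acta1 of the muscle list 121 CPM. Transcription by 1 macrophage subset is argued against, since the summed hepatocyte list varied by 2.1-fold among the diaphragm libraries, where H2-Ab1 varied by 56.7-fold. RNA of hepatocytes or muscle fibres carried into the sorted samples may account for the pattern. The tests did not decide it, because both shares fell short of the 80% set as the bound. By edgeR, 8 of the 12 hepatocyte genes and 13 of the 14 muscle genes were called lower in dura. The hepatocyte genes Ttr, Vtn, Tdo2 and Hpn overlapped between the tissues. Mean levels of Ttr, Vtn and Hpn were higher in dura (427, 30.3 and 9.2 CPM) than in diaphragm (14.2, 14 and 6.92). The dural mean of Ttr rested mostly on library 1P6 (2990 CPM). The overlap of these genes cannot decide whether liver RNA was in diaphragm, and a hepatocyte share that counts them cannot either. The sort is described only as macrophages. No other biological explanation was tested.

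Dural libraries held transcripts of meninges and bone. Of 8 tested genes of a separate meningeal stroma list, 0 (0%) were higher in every dural library than in every diaphragm library, although 5 were called higher in dura by edgeR. Slc47a1, for example, was at 32.1 to 70.8 CPM in the libraries marked P4 and had no count in 1P6. Meningeal RNA carried into the dural samples may account for the pattern and stays open. Several of the 8 genes were near 0 in some libraries, while Ptgds, at 14.9 to 132 CPM, and Zic1, at 7.18 to 61.5 CPM, were in every dural library with no count in diaphragm. A lower share of macrophages in the dural samples stays open too. The fixed fibroblast list had a median log2 fold change of -1.14 and the endothelial list of -1.99, but without diaphragm libraries 1 and 7 the medians were 1.62 and 0.19, so the negative medians rested on those libraries, and the mural list was at 1.19 and 1.57. No biological explanation was tested.

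Single libraries stood apart from the other libraries of their tissue in 10 of 208 sets of values, where the nominal rate of the outlier test gives about 10.4. Libraries of a tissue fall into clusters and some sets held only zeros, so that rate is not exact. Whether these cases exceed chance was therefore not decided. Values are log2(CPM + 1). In the dural library 1P4, Ptgds was at 7.06 (others 3.99 to 5.40), Il6 at 2.32 (others 3.45 to 4.27), Alb at 0.33 (others 0 to 0.12) and Irf4 at 3.48 (others 4.33 to 4.80). In 4P6, Serpinb2 was at 0.96 and Tnnt3 at 0.34, with no count in the other dural libraries. In 3P6, Ccl17 was at 2.49 (others 0 to 1.23). In 1P6, Clic6 was at 5.67 (others 0.77 to 2.93), and in 1P5, Ms4a1 was at 1.13 (others 0 to 0.53). The total of diaphragm library 6 was 23.4 on the log2 scale (others 24.34 to 24.84), and it was the only diaphragm library read once. The 2 diaphragm columns left out held 1496 counts (column 5) and 2115 counts (column 4), above the limit of 3 counts.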

How the results depend on the processing

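All alternatives were chosen after the column names were seen, and leaving out diaphragm libraries 1 and 7 after the values were seen. No paired analysis was possible because no column number is tied to a replicate of the labels. The count of 3472 genes called between dura and diaphragm fell to 1259 with the dural libraries summed per number (1154 of them among the 3472), to 2143 without the dural libraries marked P5, and to 1345 with an absolute log2 fold change of at least 1 required. Summing leaves 3 dural libraries and still treats the 7 diaphragm libraries as independent. The last setting is stricter by construction, and the cause of the drop without P5 was not tested. Other settings gave 2555 (without P4) to 4708 (repeat runs as separate libraries), within 1.5 times the first count. Leaving out each library in turn gave 2969 to 3585 genes. With the dural number as a random term in a voom fit, 2862 genes were called. DESeq2 called 4007, limma-voom 3451. The share higher in dura moved from 42.2% to 54.3% with upper-quartile factors and 61% with library totals. None of the named genes that were called changed direction in any setting. Of the uncalled ones, Ccr2 (0.45) was at -1.454 without P6 and -0.015 without diaphragm libraries 1 and 7, where 4157 genes were called. H2-Ab1 (-0.17) was at 0.004 with library totals, 0.208 with voom, 0.21 with the random term, 0.236 with limma on log2(CPM + 1), 0.05 with the prefixed columns, 0.021 with near-empty columns kept, 0.894 with surrogate variables, 0.358 without P4, and from -0.368 to 0.061 without 1 library. Cd74 (-0.24) was at 0.06, 0.062, 0.084, 0.037, 0.657 and 0.266 with voom, the random term, log2(CPM + 1), near-empty columns, surrogate variables and without P4. The causes were not tested. Of 103 named genes, 34 lost the call with summed dural libraries, 22 with the random term, and 10 when some single library was left out. The random term was fitted with limma-voom, which without the term already lost 14 named genes, all among these 22. Among those lost with the random term were Timd4, Csf1r, Siglech, Alox15, Prg4 and Ccr7 (limma adjusted p = 0.0502, 0.0502, 0.121, 0.227, 0.289 and 0.652). Siglech, Alox15, Prg4 and Ccr7 were also lost with voom alone (voom adjusted p = 0.0774, 0.156, 0.211 and 0.59). Of 13 lists called by camera, 1 kept its call with an estimated correlation; limma's fry also called the alternative activation and T cell lists (adjusted p = 0.0164 and 0.00733). As many genes were called in 1 of 100 splits of the 16 libraries, the real one, against at most 695 in the others. The splits treat the libraries as independent although they may share animals, so they cannot exclude chance at the level of animals. At this size the simulated test recovered 52.5% of changes of 1 on the log2 scale, so differences of that size can go undetected.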

Other observations

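Within each tissue, the libraries differed in monocyte and resident macrophage genes as well as in antigen presentation. In dura, Ccr2, the receptor that brings monocytes into tissue, was at 33.3 to 104 CPM in the 3 libraries marked P4, 248 to 278 in those marked P5 and 1460 to 1640 in those marked P6. Lyve1 went the other way, at 249 to 288, 80.4 to 131 and 4.87 to 14.5 CPM. The lectin Cd209f was at 473 to 540, 382 to 435 and 7.88 to 8.56 CPM, and the scavenger receptor Cd163 at 1320 to 1540, 884 to 1340 and 140 to 160 CPM. The integrin Itgax was at 2.89 to 10.5, 24.7 to 32.9 and 153 to 198 CPM. What the marks mean is not given in the sources used here, so these are values of single libraries and not of named subsets.

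The marks differed in how many of the 13136 genes set their 3 libraries apart from the other 6 dural libraries. For independent libraries chance gives 1.19% in each direction, but the dural libraries need not be independent. The genes set apart were, for P4, 1400 above (10.7%) and 1123 below (8.55%). For P6 they were 1912 above (14.6%) and 1810 below (13.8%), and for P5 190 above (1.45%) and 154 below (1.17%). Genes chosen after their values were seen, by the largest ratio to the other dural libraries among those with at least 20 CPM in all 3 libraries of a mark, gave for P4 the collagen Col6a1 (173 to 347 CPM, others 13.3 to 46.9) and the proteoglycan Lum (110 to 204, others 7.72 to 32.4), for example. The summed fibroblast list moved with them, at 3270 to 5780 CPM in P4, 1120 to 1370 in P5 and 725 to 1050 in P6. For P6 they gave S100a4 (119 to 144 CPM, others 5.27 to 12.9) and Ear2 (63.8 to 95.3, others 0.695 to 8.96), and for P5 Dnase1l3 (97.3 to 106 CPM, others 24.7 to 53.7).

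Diaphragm libraries showed a like spread. Ccr2 was at 19.7 and 23.7 CPM in libraries 1 and 7, at 129 in libraries 2 and 8, and at 807, 1030 and 1050 in libraries 3, 9 and 6. Lyve1 was at 1450, 1550, 785, 852, 316, 347 and 229 CPM in the same order. Retnla, low in dura, was at 1130 and 980, 2140 and 2070, and 3920, 3700 and 3440 CPM. The collagen gene Col1a1 was at 4690 and 1990 CPM in libraries 1 and 7 and at 98.3 to 236 in the other 5. Some genes did not follow this order. The scavenger receptor Marco was at 153, 384, 450 and 408 CPM in libraries 1, 7, 2 and 8 and at 1.12 to 1.78 in libraries 3, 9 and 6, and Cd207, a lectin of Langerhans cells, was highest in libraries 2 and 8 (151 and 256 CPM). Both had at most 2.12 CPM in any dural library.

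With each gene centred within its tissue, each diaphragm library was correlated with each dural library across genes, which are not independent replicates. Diaphragm libraries 1 and 7 had correlations of 0.36 to 0.60 and 0.35 to 0.58 with the libraries marked P4. Libraries 3, 9 and 6 had 0.29 to 0.34, 0.36 to 0.43 and 0.34 to 0.42 with those marked P6. Libraries 2 and 8 had their highest correlation with 4P5, at 0.24 and 0.21.

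A hypothesis from these values is that the marks P4, P5 and P6 name cell populations. Of the 280 ways to part the 9 dural libraries into 3 sets of 3, only the marks themselves (1 of 280, 0.36%) gave a mean within-set correlation across genes as high as 0.963, against at most 0.955 in the others (exact permutation, one-sided). This may hold for another shared feature of the marks too. A further hypothesis is that the numbers 1, 3 and 4 name a shared source within the marks. Of the 36 partitions whose sets each hold 1 library of every mark, only the numbers themselves (1 of 36, 2.78%) gave a correlation as high (exact permutation, one-sided). The margin was small, since the numbers and the next partition both stood at 0.923 and the lowest at 0.92. Within every mark, the library total rose from number 1 to 3 to 4, so sequencing depth cannot be told apart from a shared source. Both tests were run after the values were seen.

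In the dural library 1P6, Ttr, a gene abundant in choroid plexus and liver, stood at 2990 CPM, with 507 in 4P4, 258 in 4P5 and 4.52 to 24.6 in the other dural libraries. The same library had the highest dural level of Clic6. Among repeat runs, the pair of number 1 departed most from sampling noise, and Junb carried 20.6% of its excess chi-square, with 31444 and 42438 counts in the 2 runs. Of the columns left out, column 5 had counts in 983 genes with Apoe highest (30 counts), and column 4 in 1233 genes with H2-Ab1 highest (45 counts). Ifnb1, the gene of interferon beta, was at 4.99 to 43.7 CPM in the diaphragm libraries and at most 0.468 CPM in dura (edgeR adjusted p = 3.4e-06), while the type I interferon list did not pass camera (adjusted p = 0.706).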
